A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

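RNA was measured in 8 cultures of the budding yeast Saccharomyces cerevisiae: wild type (WT), a cac2 mutant, a psh1 mutant and a psh1 cac2 mutant, with 2 libraries of each genotype. Per the labels' protocols, overnight cultures in raffinose medium, grown in duplicate, were diluted to an OD600 of 0.1. After 2 h at 30 °C galactose was added to 4% to induce overexpression of Cse4, and the cultures then grew for 10 h. Total RNA was extracted with acid phenol, ribosomal RNA was depleted from 1000 ng of it, and strand-specific libraries were made with an Illumina TruSeq kit, per the labels' protocols. No library without Cse4 induction is analysed here, so no effect of the overexpression itself was measured.

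The authors deposited 1 table of RPKM values, that is, reads per kilobase of feature scaled to library size, on a linear scale, for 7126 features in 8 libraries. The submitters' processing notes name bcl2fastq 2.18, TopHat2 2.0.13, edgeR 3.14.0 and the genome build sacCer3, without saying what each did. The counting tool, its strand setting and the annotation are not given in the sources used here. Features were matched to the RefSeq annotation of assembly R64, of which sacCer3 is the browser name. By locus tag 6048 features matched, by symbol 114 and by synonym 7, and 957 did not match. Coordinates are those of R64 and count from 1. Because reads of near-identical copies may have been split or dropped during mapping, values of Ty elements, subtelomeric families and paralogous pairs are less certain than those of unique genes, and the same holds for overlapping features.

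The depth was not stated, so it was recovered from the values. For the 6048 features with a reference length, RPKM multiplied by length was a whole multiple of 1 step per library in 99.808% of values, with a tolerance of 0.01 reads. Reads were recovered for 7104 features, 1068 of them with a length taken as the smallest that made all values whole. The libraries held 30767522 to 34561763 reads in the listed features. The step sizes gave the library size that the authors had divided by, and its ratio to the recovered total was 1.02 and 1.04 in the WT libraries, 0.932 and 0.944 in cac2, 1.06 and 1.07 in psh1, and 0.971 and 0.975 in psh1 cac2. The deposited RPKM therefore carry a scaling per library beyond the total, which raises cac2 and lowers psh1 values relative to the plain total. A gene of 1 kb with 3 reads had an RPKM of 0.0958 in WT replicate 1 and of 0.0837 in psh1 replicate 2. Intervals and floors of this kind cover counting error alone.

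The tested values were log2(RPKM + 1), with a pseudocount of 1, for 6366 features with a mean RPKM of at least 1 over the 8 libraries, and 760 features lay below this filter. A fold change on this scale understates the change of low genes. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend) to all 8 libraries with genotype as the only term, which left 4 residual degrees of freedom and gave 3.85 prior degrees of freedom. The comparisons were each mutant against WT, psh1 cac2 against each single mutant, and the interaction, that is, the departure of psh1 cac2 from the sum of the log2 changes of the single mutants. P-values were two-sided and adjusted by Benjamini-Hochberg over the features within a comparison, with a threshold of 0.05. With 2 libraries per genotype, no count of other splits of the samples and no test for outlying libraries was made. Chi-square values per degree of freedom between the libraries of a genotype ran from 27.1 to 46.2, so no pair agreed within sampling noise and each library counted as 1 replicate.

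Gene lists were fixed before the data were examined (62 lists, covering chromatin, mating type, cell cycle, nutrition, metabolism, ribosomes, noncoding RNA, chromosome position and each of 16 chromosomes). The 58 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted within a comparison. No call of camera held in any comparison when the correlation was estimated per list. The lowest adjusted p values were then 0.517 in cac2, 0.31 in psh1 and 0.263 in psh1 cac2, each against WT, 0.402 in psh1 cac2 against cac2, 0.531 against psh1 and 0.811 for the interaction. The test fry, which asks whether the genes of a list move one way on balance, called 3, 16 and 9 lists against WT, 11 and 15 against the single mutants and 0 for the interaction. The lists of Ty reading frames and of oxidative stress genes were added after the data had been seen and were not part of these tests.

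The genes named in the text follow a rule fixed at the same time. CSE4, PSH1 and CAC2 come first. In each comparison with WT it takes the 12 higher and the 12 lower genes with the largest change among those past the threshold whose groups do not overlap, that have a symbol and are not dubious, and it takes 6 each way in the other comparisons. It adds the 1 higher and the 1 lower feature without a symbol with the largest change against WT, and, for a list that is described, up to 4 members with the smallest p or any member of a list of at most 10. Where no gene passes, it names the 5 with the smallest p each way. Named genes outside this rule are said to have been chosen after their values were seen.

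The procedure was tested on simulated data made from the real means and spreads of the 6366 features, with seeded changes. In the simulated comparison of cac2 with WT, 29.9% of genes changed 1.25-fold, 79.1% of those changed 1.5-fold and 89.4% of those changed 2-fold were called. The shares were 35.8%, 86.6% and 84.9% for psh1, 29.9%, 77.6% and 98.5% for psh1 cac2, and 14.9%, 61.2% and 95.5% for the interaction. Features without a seeded change made up 2.94% of the calls for cac2, 0.72% for psh1, 6.8% for psh1 cac2 and 5.79% for the interaction. Features were drawn independently, so libraries that deviate in many genes at once were not simulated, and the shares called may be too high for the real data. Alternatives comprised other pseudocounts, filters, normalizations, variance settings and sets of libraries, a replicate block, and leaving out each library in turn. Scaling to total reads, limma voom on the recovered reads and leaving out Ty features were added after the data had been seen. The closing section gives their effect.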

Results

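Transcript levels were compared between yeast cells lacking the ubiquitin ligase gene PSH1, cells lacking CAC2, cells lacking both, and WT, all grown while the centromeric histone H3 variant Cse4 was overproduced from a galactose-induced construct. Psh1 marks Cse4 for degradation, and Cac2 is a subunit of the histone chaperone CAF-1, which deposits histones H3 and H4 behind replication forks. The series title asks for gene expression of the mutants relative to WT under Cse4 overproduction. Each genotype had 2 libraries, with a mean of 31934670 ± 1650597 reads in WT, 33585205 ± 1152114 in cac2, 32871586 ± 825678 in psh1 and 34351292 ± 297652 in psh1 cac2 (SD, n = 2). Values are RPKM as the authors normalized them, and fold changes are on the log2(RPKM + 1) scale with their limma standard error. The first principal component held 52.1% of the variance and placed psh1 (-18.8 and -16.9) opposite cac2 (11.9 and 13.7) and psh1 cac2 (4.41 and 8.06), with WT between them (-1.96 and -0.29).

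Reads of the deleted genes were nearly absent from the strains said to lack them. PSH1 (YOL054W, chromosome XV, 228614 to 229834, + strand, a single exon) had 1076 and 1128 reads in WT and 932 and 1032 in cac2, but 0 and 2 in psh1 and 2 and 1 in psh1 cac2. CAC2 (YML102W, chromosome XIII, 68294 to 69700, + strand) had 837 and 941 reads in WT and 931 and 1155 in psh1, but 1 and 2 in cac2 and 7 and 4 in psh1 cac2.

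The overproduced gene CSE4 (YKL049C, chromosome XI, 346075 to 346764, - strand) was among the 5 features with the most reads in each library of WT, cac2 and psh1 cac2 but not in those of psh1. It stood at 15605 ± 1442 RPKM in WT, 18962 ± 1423 in cac2, 9871 ± 361.6 in psh1 and 23172 ± 529 in psh1 cac2 (SD, n = 2). CSE4 RNA fell by 0.66 (log2, SE 0.0803) in psh1 against WT (limma adjusted p = 0.0071) and rose by 0.57 in psh1 cac2 (adjusted p = 0.00604). The cac2 value of 0.28 did not pass (adjusted p = 0.101). Against psh1, psh1 cac2 had 1.23 more CSE4 RNA on the log2 scale (adjusted p = 9.87e-05). HIS3 (YOR202W, chromosome XV, 721946 to 722608), a histidine biosynthesis gene used as a selectable marker in yeast, had 5196 ± 1020 RPKM in WT, 10238 ± 2072 in cac2, 2824 ± 1.76 in psh1 and 6794 ± 148.4 in psh1 cac2. It rose by 0.98 (SE 0.156) in cac2 (adjusted p = 0.0114) and fell by 0.87 in psh1 (adjusted p = 0.0132). The increase of CSE4 in psh1 cac2 missed the threshold without either library of that strain (0.55, adjusted p = 0.0572 without replicate 1, and 0.60, adjusted p = 0.0554 without replicate 2). With quantile normalization, which gives a feature at the top the value of its rank, the change was 0 (adjusted p = 1). The HIS3 increase in cac2 was lost without cac2 replicate 1 (0.77, adjusted p = 0.0578). Its decrease in psh1 was lost without WT replicate 1 (-0.66, adjusted p = 0.0535), psh1 replicate 1 (-0.86, adjusted p = 0.0708) or psh1 replicate 2 (-0.87, adjusted p = 0.0658).

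**Figure D1:**
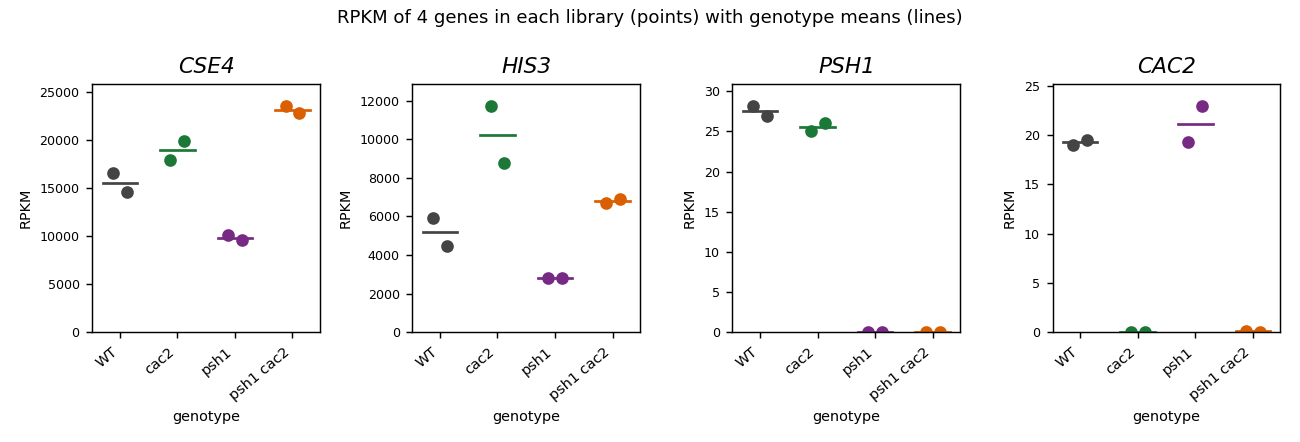
RPKM of CSE4, HIS3, PSH1 and CAC2 in each of the 8 libraries (points, linear axes from 0) with the mean of each genotype (lines). CSE4 lies lowest in psh1 (mean 9871 RPKM) and highest in psh1 cac2 (mean 23172 RPKM), HIS3 lies lowest in psh1 and highest in cac2, and PSH1 and CAC2 reads are nearly absent from the strains that lack each gene.

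In cac2 against WT, the widest change was a rise of Ty retrotransposon transcripts. Of 92 tested gag or gag-pol reading frames of Ty elements, 83 rose and 0 fell, with a median of 0.76 (log2). These copies are nearly identical and share reads, so their number overstates the number of independent measurements, and they were grouped after their values had been seen. The largest rise among genes with a symbol was that of IMD2, which encodes IMP dehydrogenase of the GTP synthesis pathway (1.20, SE 0.0858, adjusted p = 0.000546). YAR075W (1.59), a fragment of a near-identical IMD2 copy, rose with it and its value is uncertain for that reason. The other genes in the top 12 were HIS3, PRM2 (0.90), DPA10 (0.78), the sterol transporter gene PDR11 (0.75), NDJ1 (0.72), a meiotic telomere gene, MCH2 (0.72), IRC18 (0.72), the heme-responsive activator gene HAP1 (0.70), SET4 (0.70), JLP1 (0.65) and CRR1 (0.62). NDJ1 and HAP1 lie 546 and 194 bp from a Ty reading frame in the reference.

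Genes that fell in cac2 included CUE4 (-1.27, adjusted p = 0.000546), the neighbour of CAC2 on chromosome XIII, the mating-type switching endonuclease gene HO (-0.90), HMS1 (-0.89), ANB1 (-0.88), the cytochrome c isoform gene CYC7 (-0.85), AQY1 (-0.79), MF(ALPHA)1 (-0.78), the mitochondrial intron frame AI5_BETA (-0.77), FAR1 (-0.75), URA1 (-0.73) and CHA1 (-0.70). The isoleucine tRNA gene tI(UAU)D fell by 2.02 and had 57 and 61 reads in WT against 9 and 13 in cac2, at the smallest length that makes its values whole reads, so the reads may be a multiple of these. Among the a-specific genes, which mark MATa cells, 4 of 6 fell (5 when adjusted over the list alone): STE2 (-0.54), MFA2 (-0.52), AGA2 (-0.50) and STE6 (-0.29). The list lay lower than other genes (median -0.50, camera adjusted p = 0.000343, and adjusted p = 0.645 with an estimated correlation). Of 20 pheromone response genes 6 fell, among them FAR1, GPA1 (-0.44) and AGA1 (-0.42), and PRM2 rose. The pheromone response list had a median of -0.07 (camera adjusted p = 0.0125, and adjusted p = 0.645 with an estimated correlation) and was lost without cac2 replicate 1 (adjusted p = 0.0987) and with total-read scaling (adjusted p = 0.124).

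Growth-related lists had medians below 0 in cac2. Of the lists in this paragraph fry called the G1/S cluster (adjusted p = 0.0353). It did not call cytoplasmic ribosomal proteins (0.155), ribosome biogenesis (0.3), the galactose regulon (0.0764) or genes near chromosome ends (0.0664). The median of 138 cytoplasmic ribosomal protein genes was -0.34, with 9 lower and 0 higher over all genes tested and 112 lower when adjusted over the list alone. RPL31A (-0.51), RPS10A (-0.51), RPP2A (-0.51) and RPS7A (-0.46) had the smallest p. The camera adjusted p was 8.78e-30, and adjusted p = 0.696 with an estimated correlation. The 102 ribosome biogenesis genes had a median of -0.22, with 0 past the threshold in either direction (camera adjusted p = 3.71e-12, and adjusted p = 0.759 with an estimated correlation). Of 37 genes of the G1/S cluster 9 fell and 0 rose (16 lower when adjusted over the list alone), including the cyclin gene PCL1 (-0.53), the ribonucleotide reductase gene RNR1 (-0.52), and POL30, which encodes the replication clamp (-0.48). This list had a median of -0.18 (camera adjusted p = 8.69e-08, and adjusted p = 0.517 with an estimated correlation). In the galactose regulon, 4 of 12 genes fell, namely the uracil permease gene FUR4 (-0.62), GAL10 (-0.43), GAL3 (-0.29) and GAL1 (-0.49, named after its value was seen), while the activator gene GAL4 rose (0.53). Its median was -0.27 (camera adjusted p = 0.00464, and adjusted p = 0.645 with an estimated correlation), and the call was lost without WT replicate 2 (adjusted p = 0.0757) and with total-read scaling (adjusted p = 0.0668). The 222 genes within 20 kb of a chromosome end had a median of 0.13, with 12 higher and 3 lower (camera adjusted p = 4.22e-06, and adjusted p = 0.517 with an estimated correlation).

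By limma, 271 of 6366 features differed between cac2 and WT, 175 higher and 96 lower, and 1434 had an unadjusted p under 0.05. At least 2-fold changes were found for 12 of them. With the Ty frames left out, 83 of which are among the 271, 105 features were called (62 higher and 43 lower). No Ty frame fell, so the loss of lower calls came from refitting and adjusting over fewer features. Calls close to the threshold, and counts of list members that passed it, therefore depend on the Ty frames being tested. Scaling to total reads moved the median of all features by -0.12 and gave 1352 calls (163 higher and 1189 lower). Under the main settings the count was 162 without WT replicate 1 (146 of them among the 271) and 153 without cac2 replicate 1 (142 of them among the 271).

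In psh1 against WT, the genes with large decreases included some linked to detoxification and oxidative stress. Genes of histones, respiration and the G1/S and G2/M clusters rose. After PSH1 itself the largest decreases among genes with a symbol were those of OSI1 (-2.33, SE 0.417, adjusted p = 0.0129), the aryl-alcohol dehydrogenase genes AAD6 (-2.01), AAD4 (-1.85) and AAD15 (-1.71), the nitroreductase gene FRM2 (-2.00), the multidrug transporter gene FLR1 (-1.86), the glutathione transferase gene GTT2 (-1.77), PDC6 (-1.74), PMA2 (-1.57), OYE3 (-1.48) and MF(ALPHA)2 (-1.42). The AAD genes are close paralogs and may share reads. Of 45 genes listed for oxidative stress or the regulator Yap1, a list drawn up after these genes had been seen and so no independent evidence, 27 fell and 0 rose (median -0.57). The phenylalanine tRNA gene tF(GAA)N fell by 2.07 with 18 and 34 reads in WT and 3 and 5 in psh1, and tS(AGA)E rose by 1.09 from 2 reads in each WT library to 10 and 6, with the same limit on these reads as for tI(UAU)D.

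All 10 tested histone genes rose in psh1, with a median of 0.48 (camera adjusted p = 6.65e-08, and adjusted p = 0.668 with an estimated correlation). They comprised HTB2 (0.93), HTA2 (0.90), HHF2 (0.63), the linker histone gene HHO1 (0.63), HHF1 (0.50), HTZ1 (0.46), HHT2 (0.38), HTA1 (0.31), HTB1 (0.30) and HHT1 (0.28). The other large increases were GAS3 (1.00, SE 0.114, adjusted p = 0.0071), HO (0.96), CWP1 (0.94), EGO4 (0.93), the mitotic cyclin gene CLB1 (0.91), the lactate dehydrogenase gene CYB2 (0.88), SFG1 (0.86), NRM1 (0.86), a repressor of G1/S genes, NFG1 (0.86) and the glycerol transporter gene STL1 (0.85). Of 37 G1/S genes 22 rose and 0 fell (28 when adjusted over the list alone), including CLN1 (0.60), GIC1 (0.68), TOS4 (0.55) and TOS6 (0.62), with a median of 0.31 (camera adjusted p = 2.38e-14, and adjusted p = 0.31 with an estimated correlation). Of 30 G2/M genes 15 rose and 0 fell (21 when adjusted over the list alone), including NDD1 (0.44), SPO12 (0.38) and FKH1 (0.46), with a median of 0.30 (camera adjusted p = 1.33e-07, and adjusted p = 0.668 with an estimated correlation). The M/G1 list did not pass, with 1 of 27 genes higher, 0 lower and a median of 0.06 (camera adjusted p = 0.207). Fry called the histone and G1/S lists but not the G2/M list (fry adjusted p = 0.0868).

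Respiratory genes and ribosomal protein genes were higher in psh1. In this paragraph fry called oxidative phosphorylation, mitochondrial ribosomal proteins, the galactose regulon and genes near chromosome ends. It did not call cytoplasmic ribosomal proteins (fry adjusted p = 0.162) or ribosome biogenesis (0.546). Of 43 oxidative phosphorylation genes 37 rose and 0 fell (40 when adjusted over the list alone), including CYC7 (0.76), CYT1 (0.53), SDH4 (0.55) and ATP2 (0.50), with a median of 0.39 (camera adjusted p = 3.66e-20, and adjusted p = 0.668 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes 33 rose and 0 fell (54 when adjusted over the list alone), with a median of 0.23 and RSM23 (0.31) and MRPS18 (0.32) as examples (camera adjusted p = 9.59e-18, and adjusted p = 0.31 with an estimated correlation). Of 138 cytoplasmic ribosomal protein genes 27 rose and 0 fell (69 higher and 1 lower when adjusted over the list alone), including RPL9B (0.62) and RPS22B (0.42), with a median of 0.31 (camera adjusted p = 2.52e-18, and adjusted p = 0.719 with an estimated correlation). The 102 ribosome biogenesis genes instead had a median of -0.13, with 0 past the threshold in either direction (camera adjusted p = 0.000209, and adjusted p = 0.792 with an estimated correlation), a call lost without psh1 replicate 2 (adjusted p = 0.249) and turned in direction without WT replicate 1 (adjusted p = 0.812). In the galactose regulon 6 of 12 genes rose, among them the galactose permease gene GAL2 (0.69), MTH1 (0.56), GAL10 (0.40) and GAL1 (0.49), with a median of 0.37 (camera adjusted p = 0.00247, and adjusted p = 0.668 with an estimated correlation). Lower lists included the 222 genes within 20 kb of a chromosome end, of which 43 fell and 5 rose (median -0.16, camera adjusted p = 1.11e-07, and adjusted p = 0.616 with an estimated correlation). The Ty frames were also lower, with 81 of 92 past the threshold and a median of -0.41.

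By limma, 926 of 6366 features differed between psh1 and WT, 487 higher and 439 lower, and 2028 had an unadjusted p under 0.05. Of the 37 with an at least 2-fold change 36 were lower. The count was 582 when only the libraries of both groups were fitted, 203 without WT replicate 1, 484 without WT replicate 2, 268 without psh1 replicate 1 and 93 without psh1 replicate 2, and 14 of the 24 genes named by size missed the threshold in the last case. Scaling to total reads gave 1161 calls (830 higher and 331 lower).

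In psh1 cac2 against WT, small nucleolar RNAs and phosphate-uptake genes fell, and Ty frames and IMD2 rose. Of 81 tested box snoRNA and spliceosomal snRNA features 35 fell and 0 rose (47 lower and 1 higher when adjusted over the list alone), with a median of -0.42 (camera adjusted p = 7.32e-17, and adjusted p = 0.665 with an estimated correlation). Of 40 features of at least 150 nt 32 fell, with a median of -0.66, and of 41 shorter features 3 fell, with a median of -0.23. The longer class was also the more abundant (median RPKM of 354 against 29.9). Its 4 longest members, SNR84 (550 nt, 0.06), SNR19 (568 nt, 0.11), SNR30 (606 nt, 0.04) and SNR86 (1004 nt, -0.09), did not pass. The longest to fall was SNR17A (490 nt, -0.75), and all of these were looked up after their values had been seen. SNR11 fell by 1.08 (SE 0.16, adjusted p = 0.00765), SNR3 by 1.08, SNR32 by 1.03, SNR81 by 0.98, SNR34 by 0.88 and SNR82 by 0.79. The RNase MRP RNA NME1 also fell, by 0.71 (adjusted p = 0.00454), whereas the signal recognition particle RNA SCR1 had a value of 0.10 (adjusted p = 0.409) and the RNase P RNA RPR1 one of -0.11 (adjusted p = 0.394). LSR1 (-0.03, adjusted p = 0.825) and TLC1 (-0.15, adjusted p = 0.199) did not pass either. NME1, SCR1, RPR1, LSR1 and TLC1 were looked up after the values of the snoRNAs had been seen.

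**Figure D2:**
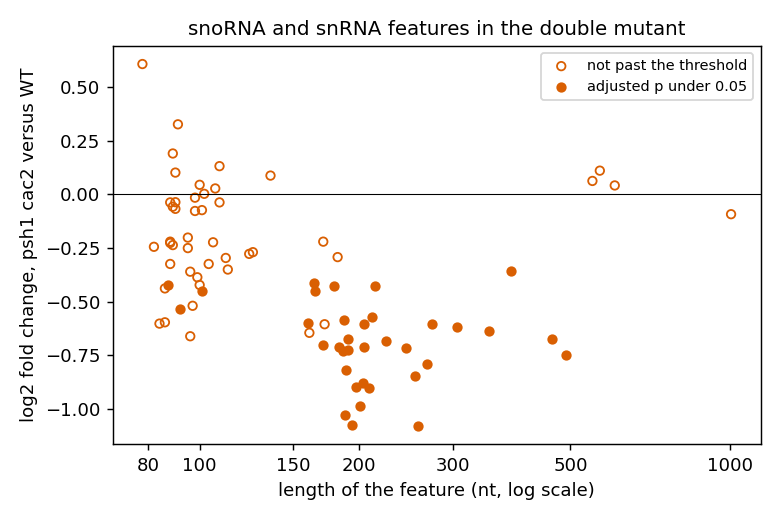
Log2 fold change in psh1 cac2 against WT of each of the 81 snoRNA and snRNA features against its length in nucleotides (log axis), filled where the limma adjusted p was under 0.05. The filled points lie mostly at lengths of 150 nt or more, where 32 of 40 features fell, below that length 3 of 41 fell, and the 4 features of at least 550 nt lie near 0.

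Of 23 genes of the phosphate regulon 13 fell and 0 rose in psh1 cac2 (16 lower when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 5.82e-10, and adjusted p = 0.263 with an estimated correlation). The phosphate transporter genes PHO89 (-1.22, SE 0.128, adjusted p = 0.00454) and PHO84 (-1.20) fell most, followed by PHM6 (-0.96) and the polyphosphate synthesis genes VTC3 (-0.59) and VTC4 (-0.58). The remaining genes with large decreases were the spore wall gene SPS100 (-1.11), CUE4 (-0.98) and the ammonium permease gene MEP2 (-0.94), and YML101C-A, a frame beside CUE4 and CAC2, fell by 1.82. Among genes with a symbol IMD2 had the largest increase (1.56, SE 0.0858, adjusted p = 0.00017), and YAR075W, its near-identical copy, rose by 1.64. HUG1, which is induced by DNA damage, rose by 1.12, LDS1 by 0.95, DDI2 by 0.77, PDR11 by 0.75, the meiotic axis gene HOP1 by 0.70, AIM20 by 0.70, PRM2 by 0.69, JLP1 by 0.66, CDA1 by 0.65, DPA10 by 0.65 and BTN2 by 0.64. Of the 92 Ty frames 80 rose and 0 fell, with a median of 0.53.

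Of 10 histone genes 5 rose in psh1 cac2 (10 when adjusted over the list alone), namely HTA1 (0.44), HHT2 (0.42), HTB1 (0.37), HHF2 (0.45) and HHO1 (0.34), with a median of 0.38 (camera adjusted p = 3.08e-07, and adjusted p = 0.665 with an estimated correlation). Of 30 G2/M genes 8 rose and 0 fell (20 when adjusted over the list alone), including SPO12 (0.52) and KIN3 (0.61), with a median of 0.35 (camera adjusted p = 3.91e-08, and adjusted p = 0.753 with an estimated correlation). Of 27 genes of the M/G1 cluster 6 fell and 0 rose, including the daughter-cell genes DSE2 (-0.53), SCW11 (-0.46) and DSE1 (-0.41), with a median of -0.18 (camera adjusted p = 9.2e-05, and adjusted p = 0.753 with an estimated correlation). Among a-specific genes STE6 (-0.49), STE2 (-0.57) and MFA2 (-0.57) fell, 3 of 6, with a median of -0.53 (camera adjusted p = 9.2e-05, and adjusted p = 0.665 with an estimated correlation). Of 42 kinetochore genes 4 rose, namely CSE4 itself, NUF2 (0.39), SPC19 (0.34) and OKP1 (0.28), and CTF19 fell (-0.48, named after its value was seen), with a median of 0.11 (camera adjusted p = 0.000436, and adjusted p = 0.263 with an estimated correlation). Fry called the histone, a-specific and kinetochore lists but not the G2/M or M/G1 lists (fry adjusted p = 0.116 for each).

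By limma, 385 of 6366 features differed between psh1 cac2 and WT, 246 higher and 139 lower, and 1578 had an unadjusted p under 0.05. Of these 18 changed at least 2-fold. The count was 227 (119 higher and 108 lower) without the Ty frames, 231 when only the libraries of both groups were fitted, 180 without WT replicate 1, 239 without WT replicate 2, 129 without psh1 cac2 replicate 1 and 13 without psh1 cac2 replicate 2, where 17 of the 24 genes named by size were lost. Scaling to total reads gave 657 calls (179 higher and 478 lower). No Ty frame fell here either, so the lower calls lost without these frames also came from the refit and the adjustment.

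**Figure D3:**
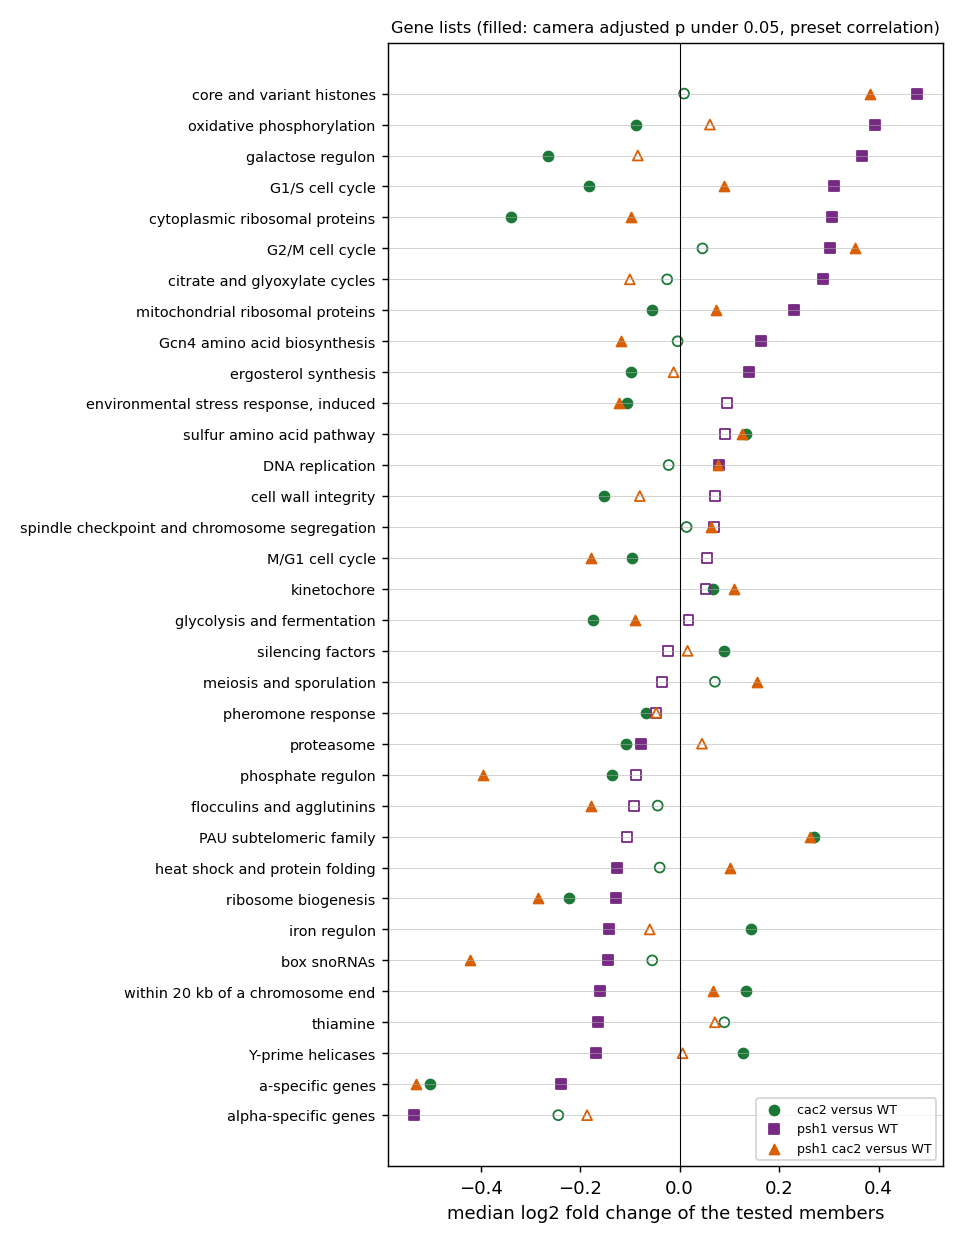
Median log2 fold change against WT of the tested members of the 34 fixed gene lists, other than whole chromosomes and ribosomal RNA, that passed camera's preset-correlation test in at least 1 of the comparisons with WT, for cac2 (circles), psh1 (squares) and psh1 cac2 (triangles), filled where the adjusted p was under 0.05. None of these calls held with an estimated correlation. Histones lie at 0.48 in psh1 and 0.38 in psh1 cac2, snoRNAs at -0.42 in psh1 cac2, and cytoplasmic ribosomal proteins at -0.34 in cac2 and 0.31 in psh1.

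Loss of PSH1 in cells already lacking CAC2 was examined by comparing psh1 cac2 with cac2. Apart from PSH1, the genes that fell most were snoRNA and snRNA genes: SNR11 (-0.95), SNR4 (-0.88), SNR14, the U4 snRNA (-0.87), SNR32 (-0.82) and SNR3 (-0.81). HUG1 (1.21, SE 0.131, adjusted p = 0.0199), POL30 (0.67), AIM20 (0.65), CYC7 (0.65), PCL1 (0.65) and SCW10 (0.62) rose. Of 81 snoRNA and snRNA features 23 fell, with a median of -0.41 (camera adjusted p = 1.94e-17, and adjusted p = 0.466 with an estimated correlation), and of 37 G1/S genes 7 rose, with a median of 0.30 (camera adjusted p = 8.93e-16, and adjusted p = 0.402 with an estimated correlation). Ribosomal RNA, which was depleted before sequencing and so reflects the preparation, was higher as a list. Its median was 2.00, with 0 of 8 features past the threshold (camera adjusted p = 0.00759, and adjusted p = 0.827 with an estimated correlation). By limma, 57 features differed, 25 higher and 32 lower, and 1515 had an unadjusted p under 0.05. This count was unstable: it was 9 without the filter on low values, 12 without the intensity trend, 23 with only the libraries of both groups, 32 without WT replicate 1 or WT replicate 2, 27 without psh1 replicate 1 or psh1 replicate 2, 2 without cac2 replicate 1, 4 without cac2 replicate 2 and 2 without either psh1 cac2 library. Scaling to total reads gave 140 (106 higher and 34 lower).

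Loss of CAC2 in cells already lacking PSH1 gave the largest number of differences. In psh1 cac2 against psh1, genes that had fallen in psh1 stood higher: OSI1 (3.23, SE 0.417, adjusted p = 0.00191), FRM2 (2.47), AAD4 (2.33), AAD6 (2.30), MF(ALPHA)2 (2.22) and AAD15 (2.00). The same 2 psh1 libraries enter this comparison and psh1 against WT with opposite sign. Genes with extreme low values in psh1 thus tend to fall in the one and rise in the other, and part of these rises may come from that. After CAC2, the genes with the largest decreases were HO (-1.60), PHO89 (-1.46), URA1 (-1.18), the glycogen phosphorylase gene GPH1 (-1.16) and EGO4 (-1.12). Of 138 cytoplasmic ribosomal protein genes 93 fell and 1 rose, with a median of -0.41 (camera adjusted p = 4.09e-20, and adjusted p = 0.64 with an estimated correlation). Of 43 oxidative phosphorylation genes 31 fell and 0 rose, with a median of -0.32 (camera adjusted p = 4.04e-13, and adjusted p = 0.64 with an estimated correlation). Of the 222 genes near chromosome ends 71 rose and 8 fell, with a median of 0.21 (camera adjusted p = 3.23e-10, and adjusted p = 0.531 with an estimated correlation), and 86 of 92 Ty frames rose. Fry called the oxidative phosphorylation and chromosome-end lists but not cytoplasmic ribosomal proteins (fry adjusted p = 0.072). By limma, 1493 features differed, 716 higher and 777 lower, 93 of them at least 2-fold, and 2456 had an unadjusted p under 0.05. The count was 572 without psh1 replicate 1, 682 without psh1 replicate 2, 763 without psh1 cac2 replicate 1 and 502 without psh1 cac2 replicate 2, and scaling to total reads, which moved the median of all features by -0.13, gave 2619 (427 higher and 2192 lower).

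The fold changes of cac2 and psh1 against WT ran in opposite directions across genes (Pearson r = -0.209, Spearman rho = -0.228 over 6366 features, which are not independent replicates). Unchanged groups simulated against the same WT libraries gave a mean r of 0.498. The covariance was -0.0131 against a simulated 0.0067, a difference of -0.0198. Of the features called in both comparisons, 146 changed in opposite directions, 2 rose in both and 8 fell in both, where independent lists would share 19.4, 13.4 and 6.6. Without the Ty frames 66 were opposite, against 12.7 for independent lists, and r was -0.158. Examples are HO, CYC7, PCL1, RNR1, POL30, GAL1 and GAL10, lower in cac2 and higher in psh1, and HIS3, which was higher in cac2 and lower in psh1. The correlation was 0.022 without WT replicate 2 and -0.128 without WT replicate 1, where unchanged groups that share a single WT library gave 0.603 to 0.718 in 100 simulations added after these values had been seen. With a separate WT library as the control of each mutant, which removes the shared values, it was -0.343 and -0.284 in the 2 ways to assign them.

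**Figure D4:**
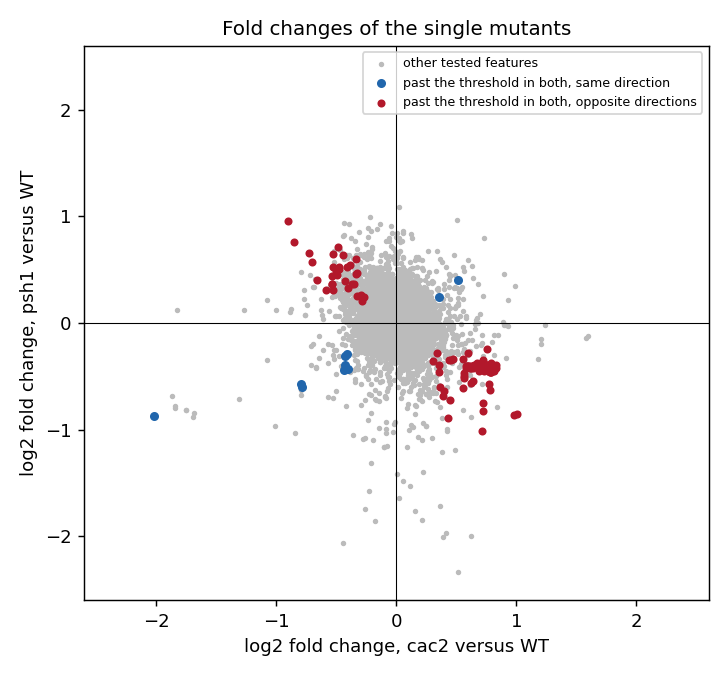
Log2 fold change against WT of each tested feature in cac2 (horizontal) and psh1 (vertical), with axes that end at 2.6 in each direction and leave out 2 features, the deleted genes. Of the features past the threshold in both comparisons 146 lie in the quadrants of opposite direction (red) and 10 in those of the same direction (blue).

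Some features called in both comparisons moved in opposite directions between psh1 cac2 and psh1, and 0 did so between psh1 cac2 and cac2. Fold changes of psh1 cac2 and cac2 against WT had r = 0.576, which lies inside the range of 0.419 to 0.578 that shared controls alone gave, and a covariance 0.0255 above the simulated value, with 124 features higher in both, 29 lower in both and 0 opposite. Independent lists would share 6.8, 2.1 and 7.5. For psh1 cac2 and psh1, r was 0.14 against a simulated 0.499, with a covariance difference of 0.0022, 43 features higher in both, 21 lower in both and 107 opposite (18.8, 9.6 and 27.6 for independent lists). Much of this difference came from the Ty frames. Without them 44 features were higher in both, 29 lower in both and 0 opposite for cac2, and 43, 21 and 27 for psh1. Part of each overlap may come from the shared controls, since 2 WT libraries cannot be split into groups of 2. Comparisons that share no library gave r = 0.581 for the effect of losing CAC2 with and without PSH1, and r = 0.378 for the effect of losing PSH1 with and without CAC2. These include the deleted gene itself, which falls in both. Without CSE4, the deleted genes and their neighbours r was 0.564 and 0.338. Without the Ty frames it was 0.526 for losing CAC2.

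The interaction asked whether psh1 cac2 departed from the sum of the single-mutant changes. By limma, 1 of 6366 features passed, the tRNA gene tI(UAU)D (3.36, SE 0.168, adjusted p = 0.000318), and 866 had an unadjusted p under 0.05, while limma voom on the recovered reads called 6. The genes next in line, none of them past the threshold, were CSE4 (0.95, adjusted p = 0.0802), AAD6 (1.90), YFL057C (1.87), YOL163W (0.64) and GTT2 (1.69) above 0, each with an adjusted p of 0.0802, and SNR52 (-0.99, adjusted p = 0.0872), CMI8 (-0.47), BDH1 (-0.60), YLR152C (-0.71) and YER039C-A (-0.64) below 0. AAD6 and YFL057C match 1 locus of the reference (chromosome VI, 14305 to 15431), so they may not be separate genes. Without cac2 replicate 2 the interaction gave 41 calls. CSE4 passed in 4 of 19 other settings, among them that one (1.03, adjusted p = 0.0206) and limma voom (0.95, adjusted p = 0.038), and its adjusted p ran from 0.00108 to 0.292. The lowest came with quantile normalization, where the interaction was smaller (0.50) because a feature at the top takes the value of its rank. A replicate block called 130 features, CSE4 among them (limma adjusted p = 0.0216), but the replicate numbers are not known to pair cultures.

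Chromosome copy number was examined through expression, since Cse4 and its regulators act on chromosome segregation. The median log2 value of the tested genes of each of 16 chromosomes, relative to the WT mean, ran from -0.06 (chromosome 3 in psh1 replicate 1) to 0.07 (chromosome 1 in cac2 replicate 1). Of the 16 chromosome lists, chromosome 1 passed in cac2 against WT (107 genes, 6 higher and 0 lower, median 0.05, camera adjusted p = 0.0479, and adjusted p = 0.517 with an estimated correlation; fry adjusted p = 0.0349), with 0.07 and 0.04 in its libraries. Its median was -0.07 with total-read scaling, where the call held relative to other genes (adjusted p = 0.0165). The call was lost without a filter on low values (0.0978), with a minimum of 5 RPKM (0.101) and with quantile normalization (0.153). The adjusted p was 0.142 without WT replicate 1, 0.0587 without WT replicate 2, 0.118 without cac2 replicate 1, 0.0575 without cac2 replicate 2, 0.0622 without psh1 replicate 1 and 0.0616 without psh1 replicate 2. Among the comparisons with WT, fry also called chromosome 3 (adjusted p = 0.0181) and chromosome 15 (0.0461) in psh1 and chromosome 1 (0.018) in psh1 cac2. In psh1 cac2 against psh1 it called chromosome 1 (0.01), chromosome 3 (0.00901) and chromosome 11 (0.0456). A chromosome present in 3 copies for every 2 of the others would lie at 0.58 if expression followed copy number. A gain in only part of the cells of a culture would give a smaller value, so these medians cannot decide on a mixed culture. The 185 tested genes within 10 kb of a centromere had medians of -0.02 in cac2, -0.01 in psh1 and -0.01 in psh1 cac2, none past the list test (camera adjusted p = 0.888, 0.878 and 0.685), and the sign of these medians changed with the scaling.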

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

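The tests of galactose induction, of both library scalings, of the HIS3 to CSE4 ratio and of short-RNA loss were chosen only after the results they measure had been seen, as was total-read scaling.

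By the test of the interaction, the effect of losing CAC2 differed between cells with and without PSH1 for 1 of 6366 features. A replicate block, whose numbers are not known to pair cultures, gave 130. Under the main settings the 1 feature was the tRNA gene tI(UAU)D, with an interaction of 3.36 on the log2 scale. Its reads were 57 and 61 in WT, 9 and 13 in cac2, 31 and 34 in psh1, and 78 and 94 in psh1 cac2, at the smallest length that makes its values whole. Among gene lists, camera at a preset correlation called 16. Interaction medians above 0 were found for alpha-specific genes (0.49), meiosis and sporulation (0.18), heat shock and protein folding (0.21), ribosome biogenesis (0.094), DNA damage response (0.061), the proteasome (0.22), thiamine genes (0.17), genes within 20 kb of a chromosome end (0.078) and ribosomal RNA (2.80), which was depleted before sequencing and so reflects the preparation. Medians below 0 were found for M/G1 genes (-0.15), Gcn4 targets of amino acid biosynthesis (-0.29), the sulfur amino acid pathway (-0.11), oxidative phosphorylation (-0.24), citrate and glyoxylate cycles (-0.29), mitochondrial ribosomal proteins (-0.09) and box snoRNAs (-0.34). With an estimated correlation 0 of these lists passed (lowest adjusted p = 0.811), and fry called 0. Several calls also rested on single libraries. Ribosome biogenesis turned in direction without WT replicate 1 (adjusted p = 0.25) and was lost without cac2 replicate 2 (0.518), psh1 replicate 2 (0.938) or psh1 cac2 replicate 1 (0.805). The DNA damage response was lost without WT replicate 2 (0.13), cac2 replicate 1 (0.192), psh1 replicate 2 (0.121) or psh1 cac2 replicate 2 (0.0876). The sulfur pathway was lost without WT replicate 1 (0.977), cac2 replicate 2 (0.281), psh1 replicate 1 (0.103) or psh1 cac2 replicate 2 (0.0705), M/G1 genes without cac2 replicate 2 (0.0711), and meiosis and sporulation with quantile normalization (0.219). With a minimum of 5 RPKM the calls of meiosis and sporulation, the DNA damage response and the sulfur pathway were lost as well.

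CSE4 RNA was lower in psh1 than in WT although all strains were induced alike per the labels. The median of GAL1, GAL7 and GAL10 was 0.395 in psh1, opposite in sign to the change of CSE4, so these native genes showed no weaker induction. They need not track the construct, however. The galactose regulon had a median of -0.27 in cac2 and -0.08 in psh1 cac2, where CSE4 stood at 0.28 (not past the threshold) and 0.57. Weaker induction of the construct itself is therefore left open. The scaling is argued against by a CSE4 change of -0.603 with total-read scaling. Another explanation that stays open is fewer copies of a construct that carries both CSE4 and HIS3, since the log2 ratio of HIS3 to CSE4 reads changed by -0.208 (95% interval -0.816 to 0.401). The labels do not describe the construct. In cac2 the same ratio changed by 0.696 (0.087 to 1.304, with the spread pooled over the genotypes). It stood at -0.675 and -1.244 in cac2 replicates 1 and 2 and at -1.548 and -1.762 in WT. Both cac2 libraries lay above WT, but they lay far apart and the size of the change rests largely on replicate 1. Whether copy number alone could cause the higher HIS3 there is left undecided.

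The opposite fold changes of cac2 and psh1 were set against 2 explanations. Shared WT libraries are not counted among them, since sharing can only raise the correlation, which was -0.284 at its highest with separate WT libraries. Removing a quadratic trend on gene length and GC content left -0.243 over 5979 genes, from -0.247 before, which argues against such a bias as the whole cause. Leaving out the ribosomal protein, ribosome biogenesis, induced stress response, oxidative phosphorylation and Ty lists left -0.126 over 5857 features, so these lists carry part of the pattern but not all of it. A biological cause in the genotypes is a hypothesis, and 2 cultures per strain leave it open. The strains also differed from WT in CSE4 RNA (-0.66 in psh1 and, short of the threshold, 0.28 in cac2), and this difference was not separated from genotype.

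The lower snoRNAs of psh1 cac2 were set against 3 technical explanations. For loss of short RNAs during preparation, the change was set against length (Spearman rho = -0.482 across 81 features), and features under 150 nt fell less than longer ones. This cannot decide the question, since the shorter class was poorly recovered (median RPKM of 29.9 against 354). Within the longer class the 4 longest features did not pass, so a loss by size is left open. The list median was -0.389 at its highest under 3 other scalings, which argues against the scaling. Libraries of 1 genotype that differed in ribosomal RNA content differed in the list median by at most 0.165, against a change of -0.42, which argues against the efficiency of depletion as the whole cause. Lower production or stability of snoRNAs in psh1 cac2 may underlie the pattern, as an untested hypothesis, and other differences between the preparations were not tested.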

How the results depend on the processing

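Total-read scaling, limma voom on recovered reads and leaving out Ty frames were chosen only after the data had been seen, and the planned edgeR analysis of recovered reads was not run (limma voom took its place). In the counts of features, comparisons are given in the order cac2, psh1 and psh1 cac2 against WT, psh1 cac2 against cac2 and against psh1, and the interaction. Unless a cause is given, the cause was not tested.

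Requiring a change of at least 2-fold as well left 12, 37, 18, 3 and 93 features. A replicate block gave 821 (312 higher and 509 lower, against mostly higher without it), 1625, 984 (455 higher and 529 lower, likewise turned), 520 and, for the interaction, 130, with CSE4 among them (adjusted p = 0.0216), and chromosome 1 in cac2 then missed the threshold (0.0656), but the replicate numbers are not known to pair cultures, and the deviations from the genotype mean correlated by 0.038 to 0.443 between genotypes, above 0 in each of the 6 pairs. Total-read scaling gave 1352 for cac2, 657 for psh1 cac2, 140 against cac2 and 2619 against psh1, since it moves all features of a library together. Leaving out Ty frames gave 105 for cac2 and 227 for psh1 cac2. Fitting only the libraries of the groups compared, with fewer residual degrees of freedom, gave 582, 231 and 23 for psh1, psh1 cac2 and psh1 cac2 against cac2. That last count was 9 without a filter and 12 without a trend. The interaction gave 5 with quantile normalization and 6 with limma voom.

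Leaving out 1 library gave 153 to 254, 93 to 826, 13 to 373, 2 to 32, 502 to 1489 and 1 to 41 features, and 15 to 24, 18 to 21, 16 to 22, 13 to 19, 19 to 23 and 15 to 20 lists. The lone library of a genotype is then assumed to vary like the other groups. Under an estimated correlation 0 lists passed in any comparison. Total-read scaling called 15 lists for cac2, quantile normalization 14 for psh1 cac2, and fry 3 for cac2, 9 for psh1 cac2, 11 against cac2 and 0 for the interaction.

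Some lists changed sign, and their adjusted p over the 8 fits without 1 library is given as a range. The proteasome in cac2 turned with quantile normalization (0.628) and without cac2 replicate 1 (0.568; range 7.23e-08 to 0.92). The induced environmental stress response turned without WT replicate 2 in cac2 (0.432; range 1.01e-09 to 0.432) and in psh1 cac2 (0.78; range 3e-11 to 0.852). Without WT replicate 1 the sign turned for ribosome biogenesis in psh1 (0.812; range 3.21e-16 to 0.812) and the interaction (0.25; range 1.37e-13 to 0.938), and for cytoplasmic ribosomal proteins in psh1 cac2 (0.348; range 1.2e-13 to 0.594).

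The correlation of cac2 with psh1 was -0.157 with a pseudocount of 0.1, -0.267 with 5, -0.141 without a filter and -0.163 with quantile normalization, and ran from -0.22 to 0.022 when 1 library was left out. The range was 0.45 to 0.669 for cac2 with psh1 cac2, 0.074 to 0.28 for psh1 with psh1 cac2 (0.093 with a pseudocount of 5), 0.475 to 0.602 for losing CAC2 and 0.312 to 0.398 for losing PSH1 in both backgrounds.

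The largest chromosome median was 0.0382 in cac2, -0.0498 in psh1 and 0.0408 in psh1 cac2 with a pseudocount of 5, 0.0416 in cac2 and 0.0395 in psh1 cac2 without a filter, and 0.0413 and 0.0387 with a minimum of 5 RPKM. Quantile normalization gave -0.0445 in psh1 and 0.0232 in psh1 cac2, and median centring 0.0663 in psh1 cac2. Total-read scaling turned the sign, to -0.1425, 0.0663 and -0.0963. It moved the median of all features by -0.12, 0.05 and -0.08 in these comparisons, so this turn goes with the shift of whole libraries and is no sign of a chromosome change. Without 1 library the values ran from 0.0379 to 0.0954, -0.0595 to -0.0353 and -0.0263 to 0.0684, and the sign for psh1 cac2 turned without WT replicate 1.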

Other observations

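The look at IMD3 was chosen only after its value was seen, and the tests of Yap1-linked genes and of Ty neighbours were set down before their results.

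IMD2 and IMD3 encode IMP dehydrogenase, and they moved apart in cac2. Of the 3 tested genes of this family 1 rose, 1 fell and 1 did not pass there, with a median of -0.46. IMD2 rose by 1.20 and IMD3 fell by 0.66 (limma adjusted p = 0.0128), and in psh1 IMD3 rose by 0.40 (adjusted p = 0.0448) whereas IMD2 did not pass (-0.20, adjusted p = 0.154). IMD3 was picked after its value was seen, and reads shared between these paralogs were not examined.

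Genes linked to the oxidative stress regulator Yap1 may have fallen in psh1 beyond those named for their size. With the 45 features of largest change each way, among those past the threshold in psh1 against WT and in psh1 cac2 against psh1, removed, 26 listed genes were left, with a median of -0.271. Of these 10 fell and 0 rose (camera p = 4.26e-05 at a preset correlation, and p = 0.237 with an estimated correlation). The values go with a shared fall of the group, as a hypothesis, since the list was drawn up after its strongest members had been seen.

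A spread of the Ty increase in cac2 to neighbouring genes was examined as a hypothesis, since HAP1 and NDJ1 lie near Ty frames. The 48 genes within 1 kb of a Ty frame had a median of 0.02, with 4 higher and 2 lower (camera p = 0.355, and p = 0.539 with an estimated correlation). The median lies near 0 over members that went both ways, and Ty insertions of these strains may differ from the reference, so this is left undecided.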
